A study of Mus musculus with 8 samples.

How the data were processed

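Whole liver of wild type mice and of mice with a liver-specific Cdc42 knockout was collected at 2 months of age, with 4 biological replicates of each genotype and 1 array per animal. Livers were rinsed through with PBS and put in Trizol, and biotin-labelled cRNA was made with a 3′ IVT kit and hybridized to Affymetrix mouse arrays, per the labels' protocols. The deposited log2 signals were made with MAS5 according to the labels, which give no version and no scaling target, and the authors' values run from 0 to about 16 on each array. The authors' detection calls (Present, Marginal or Absent) stand beside the deposited signal of every probe set. The authors also deposited a p-value of the genotype comparison for each probe set, which equals an unequal-variance test of the log2 columns, with no adjustment per the file headers. The deposited fold ratios compare group means, and 4 pairs of single arrays, as sizes of at least 1 with the direction in a separate column, per the file headers. A further deposited table holds the same log2 values and was not run separately. In the authors' deposited table, 10540 probe sets have a p-value below 0.05, and 3156 of them are also at least 2-fold different, 1866 higher and 1290 lower in knockout.

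Gene symbols came from the deposited annotation, matched to current symbols by Entrez ID for 34158 probe sets and by symbol for 482. For 2823 the symbol was kept as deposited, 6114 had none, and 1460 with several symbols were left unnamed. The 64 control probe sets were left out of the gene tests, and the Actb and Gapdh controls served for the 3′ minus 5′ measure. Probe sets called Present on at least 4 of the 8 arrays were kept, and each gene was represented by the kept probe set with the highest mean signal over all arrays, which gave 12139 genes. Of the changed genes, 1881 had more than 1 kept probe set, and in 1545 of these all had the same sign. Probe sets that can read several transcripts, and members of the Mup, Cyp2c, Cyp3a, Sult and Ugt2b families, are uncertain for a single gene.

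The deposited log2 signal was compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend), knockout minus wild type, with no covariate, and p-values were adjusted with the Benjamini-Hochberg method over all genes tested. Changed means an adjusted p below 0.05, and the count with at least a 2-fold difference is given beside it. Intervals for Cdc42 are 95% intervals from limma's standard error, in which the spread between arrays is drawn toward that of probe sets of like signal. For a gene called Absent on all arrays of 1 group, the fold is a bound: the mean of the detected group against the mean of the other group with each array's signal raised to at least the 5th percentile of that array's Present signals. The same bound is given for named genes with at least 2 arrays of the lower group under that floor, although the largest folds were ranked by the signal itself. That floor was chosen after the values were seen, as the more cautious of 2 tried (the other was the lowest Present signal), and both gave the same genes by size of bound. Single measures per array were compared with a 2-sided exact permutation test, whose smallest possible p with 4 against 4 is 0.0286. The number of arrays limits the precision of every value.

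Gene lists of liver pathways, cell types and technical markers were fixed before the data were examined, as were the tests, the filter and most alternatives. Of 41 lists, 39 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. Medians of lists were also set against 10000 random lists matched on mean signal, which was added after seeing the data. The genes named by the text follow a rule of the same date. It takes Cdc42, then the 12 largest increases and the 12 largest decreases among changed genes with groups that do not overlap and detection in both groups. It adds up to 3 genes per direction with the largest bound, up to 4 members of each list in the direction of its shift and up to 2 in the other, and 5 sex-linked genes. The text names a part of the list members so chosen, and 1 gene and 1 gene list within these counts are not reported here. Genes outside that rule are said to be chosen after their values were seen.

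Alternatives covered quantile normalization, median centring, a floor of 16, a pseudocount of 32, no filter and a stricter filter, and every probe set or the mean of a gene's probe sets. Median centring gave all arrays the same median over the probe sets called Present on every array. The alternatives also covered eBayes without the trend or with robust settings, array weights, the animal number series as a block, a plain test per gene, and leaving out each array. Cyclic loess normalization, the array pairs of the deposited fold columns as a block, and each animal number series alone were added after seeing the data. The gene and list tests were tested on simulated data for 12139 genes with 4 arrays against 4. They recovered 22.4% of genes changed by 0.5, 71.6% of those changed by 1 and 93.9% of those changed by 2 on the log2 scale, called 11 unchanged genes and gave 0 wrong signs. With no list changed in the simulation, camera called 0 lists, and with 1 list raised by 0.5 it called 1. The simulated genes varied independently of each other, while the estimated correlation within the oxidative phosphorylation list was 0.534. The simulation therefore cannot show how camera with its preset correlation treats lists of correlated genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.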

Results

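RNA from the whole liver of 2-month-old mice was measured on 8 Affymetrix mouse expression arrays, 4 from wild type animals and 4 from animals labelled as lacking Cdc42 in the liver, 1 array per animal. Cdc42 is a small GTPase with a known part in cell polarity and the actin cytoskeleton, and the comparison asks which liver transcripts differ when the gene is deleted in that organ. The deposited values were log2 signals for 45101 probe sets, with a Present, Marginal or Absent call for each on every array. Median log2 signals ran from 6.44 to 6.63 over the 8 arrays. The animal numbers in the sample titles fell into a lower and a higher series, each with 2 arrays of both genotypes. Differences below are labelled knockout minus wild type on the log2 scale, with ± giving limma's standard error, n = 4 per group, and adjusted p from limma over 12139 genes unless said otherwise.

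Cdc42 signal was not lower in the livers labelled as knockout. Its 3 probe sets, in the order of their identifiers, differed by 0.10 ± 0.09, -0.04 ± 0.09 and 0.05 ± 0.11, with limma adjusted p of 0.497, 0.817 and 0.830. The lower 95% limits put the labelled knockout level at no less than 92.4%, 83.5% and 85.9% of wild type. The alignments given for the first and the third lie on chromosome 4 from 136875615 to 136876592 on NCBI Build 37, with a second alignment on chromosome X, while the second is aligned from 136875614 to 136913662 on chromosome 4 alone. The labels do not say which part of the gene was removed, and a probe set outside the deleted part checks nothing about the genotype. Every direction given here therefore rests on the genotype labels.

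The labelled knockout arrays also differed in measures of the RNA and of the arrays. The 3′ minus 5′ log2 signal of Actb was 0.52 ± 0.06 (SD, n = 4) against 0.70 ± 0.06 in wild type, and that of Gapdh -0.40 ± 0.02 against -0.27 ± 0.07. The share of probe sets called Present was 54.2% ± 0.713 (SD, n = 4) against 48.6% ± 1.46. The brightest probe sets, taken as the same number on each array, held 38.4% ± 1.17 of the summed signal (SD, n = 4) against 43.4% ± 1.22. Each of these measures had a 2-sided exact permutation p of 0.0286, the smallest that 4 arrays against 4 allow, and 0.0343 after Benjamini-Hochberg adjustment over 6 measures. Leaving out 1 array raised the exact permutation p to 0.0571 for the Actb measure without wild type replicate 1, 2 or 4 or labelled knockout replicate 3 (-0.18 to -0.16 between the groups), and for the Gapdh measure without labelled knockout replicate 1, 2, 3 or 4 (-0.13 to -0.12). The groups still did not overlap whichever array was left out. The lowest wild type values were 0.627 for Actb and -0.357 for Gapdh, against highest labelled knockout values of 0.606 and -0.382. Few assignments of the remaining arrays are possible, so the higher p does not show that the difference rests on those arrays. Median log2 signal was 6.53 against 6.50, with an exact permutation p of 0.686.

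Liver transcripts differed widely between the genotypes, with 158 changed genes called Absent on every wild type array and 9 on every labelled knockout array. The noncoding RNA H19, an imprinted transcript of fetal liver, was at least 80-fold higher in labelled knockout liver (limma adjusted p = 4.46e-06), and the cell surface protein gene Ly6d at least 141-fold higher (adjusted p = 8.3e-07). Both were called Absent on all 4 wild type arrays, as was Igdcc4, at least 31.8-fold higher (limma adjusted p = 3.81e-05). Hsd3b5, a steroid dehydrogenase of male mouse liver, was Absent on all 4 labelled knockout arrays and at least 168-fold lower (limma adjusted p = 4.46e-06, at least 268-fold without wild type replicate 1). The organic anion transporter gene Slco1a1 fell by 7.96 ± 1.06 on the log2 scale (limma adjusted p = 0.00048).

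Of the 12139 genes tested, 4145 changed at a limma adjusted p below 0.05, 2450 of them higher and 1695 lower in labelled knockout liver. Centring each array on the median of the probe sets called Present on every array gave 1913 higher and 2338 lower genes. The share of higher genes was then 45%, against 59.1% in the main fit. At least 2-fold changes numbered 827 higher and 249 lower. Groups did not overlap for 3637 of the changed genes, and for 34.1% of all tested genes against 2.86% by chance. With the animal number series as a block, 2675 genes were higher and 1934 lower. All 4145 changed genes had the same sign in both series. They were called on the same arrays, which favours equal signs, so this is no separate replication. Within the lower and the higher series alone, 2236 and 2782 genes passed, with 2 arrays against 2.

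Among changed genes detected in both groups, the largest increases reported here were led by Ubd, which encodes a ubiquitin-like modifier, at 6.05 ± 0.88 (limma adjusted p = 0.000737). Plet1 rose by 4.92 ± 0.45 and Lcn2, an iron-siderophore binding protein of the acute phase, by 4.38 ± 0.87. The collagen receptor gene Ddr1 (4.24 ± 0.18, with 3 of 4 probe sets of that sign) and the claudin gene Cldn7 (4.23 ± 0.69) followed. Ddr1 kept its call in all 25 alternatives, but its difference ranged from 1.74 to 4.40 among them. Epdr1, Smoc2, Treh, Serpinb6b, Rragd and Esco2 rose by 3.70 to 4.12. The largest decreases after Slco1a1 were in the sulfotransferase gene Sult2a8 (-5.37 ± 0.42) and in Mup3 (-5.28 ± 0.66) and Mup10 (-4.95 ± 0.69), which encode major urinary proteins. Leaving out 1 array moved some of these folds by over 1.5 times, to log2 differences of 5.0 for Ubd and 5.20 for Lcn2 without wild type replicate 1, 4.87 for Cldn7 without wild type replicate 2 and 3.60 for Lcn2 without wild type replicate 4. Without labelled knockout replicate 2 those of Mup3 and Mup10 were -4.59 and -4.28, without labelled knockout replicate 4 that of Myom2 was -3.26, and that of Slco1a1 lay between -8.83 and -7.12 when labelled knockout replicate 1, 2, 3 or 4 was left out. Where at least 2 arrays of the lower group were under the background floor, the fold against that floor was smaller. It was at least 27.5-fold for Ubd, 13.3-fold for Epdr1, 6.18-fold for Cldn7 and 5.75-fold for Esco2 higher, and at least 102-fold for Slco1a1 and 5.16-fold for Mkx lower. Near-identical copies of the Mup and sulfotransferase genes can share probes, so these values are uncertain for a single gene. Sdr9c7, the fatty acid elongase gene Elovl3, Myom2, the bile acid synthesis gene Cyp8b1, Mkx, Cnmd, Serpina12 and Rgs16 fell by 2.81 to 4.39. Serpina4-ps1 was at least 28.6-fold lower (at least 17.5-fold without wild type replicate 3), Absent on every labelled knockout array. Ces1f, also Absent there, was at least 7.08-fold lower (limma adjusted p = 0.0274), with a bound of 10.7-fold without wild type replicate 2 and 2.47-fold without wild type replicate 1, where the log2 difference was -2.58 (adjusted p = 0.00317). Leaving out labelled knockout replicate 1, 3 or 4 ended the Ces1f call, with limma adjusted p of 0.0598 to 0.0682.

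**Figure D1:**
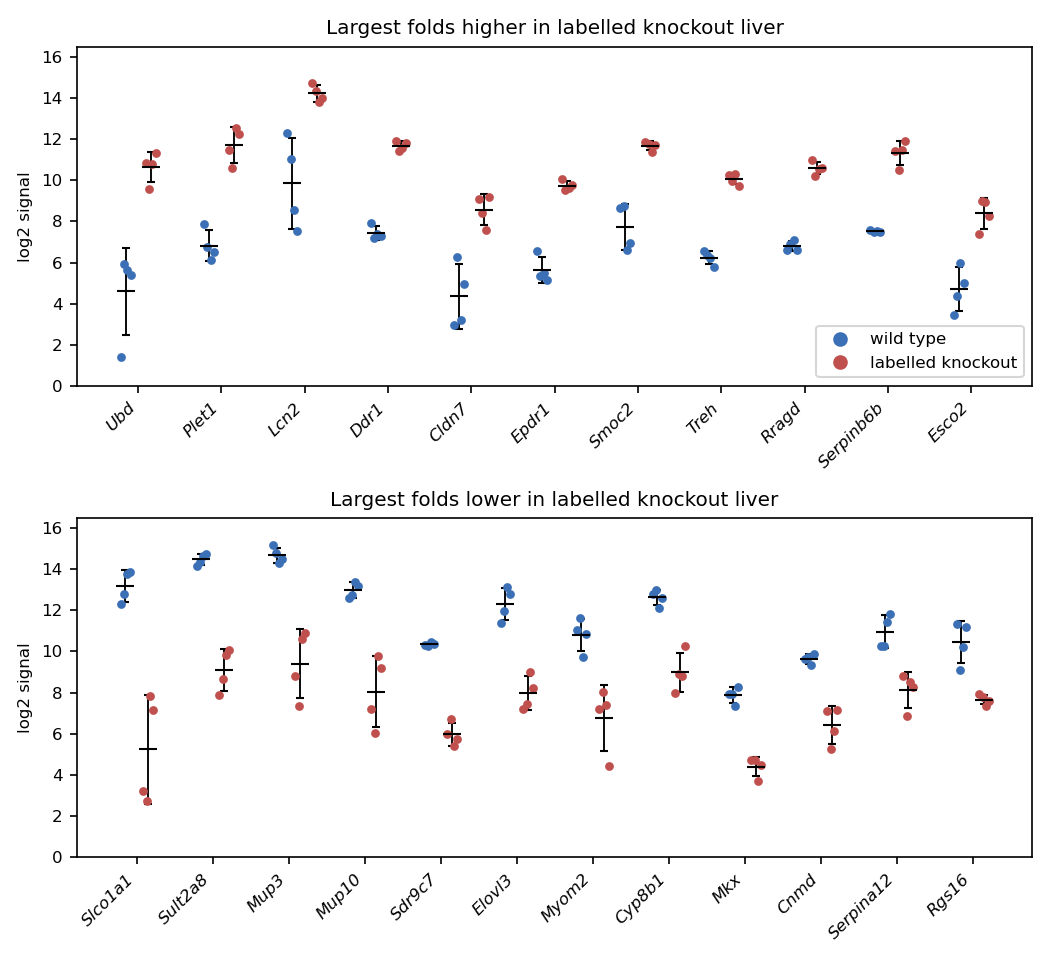
Log2 signal of 11 of the genes with the largest increases and of the 12 with the largest decreases among changed genes detected in both groups, as points per array (4 wild type, 4 labelled knockout), with bars at the mean ± SD. Every labelled knockout array lies above, or below, every wild type array for each gene.

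Genes of the actin cytoskeleton list, which also holds a tubulin gene, rose in labelled knockout liver. Of 43 tested members, 33 rose, 1 fell and 9 did not pass (34 and 1 adjusted over the list alone), with a median difference of 0.73, and 0.50 and 0.95 within the lower and the higher animal number series. Anxa2, a membrane-associated actin-binding annexin, rose by 2.70 ± 0.15, the beta-tubulin gene Tubb6 by 2.15 ± 0.21 and Arpc1b, a subunit of the Arp2/3 complex, by 1.52 ± 0.10. The list had a camera adjusted p of 3.03e-11, and an adjusted p = 0.139 with an estimated correlation. Actb, the member that fell, was at -0.29 ± 0.08 (limma adjusted p = 0.0244). Its sign turned after quantile normalization (0.06, limma adjusted p = 0.469), and its call was lost without wild type replicate 4 (-0.23, adjusted p = 0.0585) or labelled knockout replicate 3 (-0.25, adjusted p = 0.0625).

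Genes that act with Cdc42 rose more often than they fell. Of 35 Cdc42 effector and regulator genes, 14 rose, 1 fell and 20 did not pass (14 and 1 adjusted over the list alone), with a median of 0.34, and 0.22 and 0.39 within the series. The scaffold gene Iqgap1 rose by 1.35 ± 0.15 and the Cdc42-activated kinase gene Pak1 by 1.27 ± 0.15, and Iqgap2 fell by 0.65 ± 0.09 on the log2 scale. That list had a camera adjusted p of 0.00669, and an adjusted p = 0.219 with an estimated correlation.

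Cell junction genes went both ways. Of 31 members, 13 rose, 5 fell and 13 did not pass (14 and 5 adjusted over the list alone). The keratin genes Krt8 and Krt18 rose by 1.49 ± 0.10 and 1.36 ± 0.08, while Ceacam1, an adhesion molecule of the bile canaliculus, fell by 0.86 ± 0.11 and the claudin gene Cldn12 by 0.69 ± 0.11 on the log2 scale. The median was 0.28, and 0.25 and 0.21 within the series (camera adjusted p = 0.0495, adjusted p = 0.246 with an estimated correlation). Leaving out wild type replicate 1 or 2 or labelled knockout replicate 1 or 4 ended that call, with camera adjusted p of 0.0529, 0.0501, 0.0846 and 0.0651. It also ended with the deposited array pairs as a block (0.0629), a floor of 16 (0.0501) and a pseudocount of 32 (0.0510). Of 23 YAP target genes, 10 rose, 2 fell and 11 did not pass (10 and 2 adjusted over the list alone), with Nt5e at 2.00 ± 0.20, the matricellular growth factor gene Ccn2 at 1.78 ± 0.26 and Ajuba at 1.37 ± 0.16, and Amotl2 at -0.46 ± 0.11. The YAP list had a median of 0.41, and 0.58 and 0.36 within the series (camera adjusted p = 0.00956, adjusted p = 0.149 with an estimated correlation). Within the higher series alone, the calls of the junction and YAP lists were lost, at adjusted p of 0.0614 and 0.0728.

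Cell cycle genes rose strongly, together with p53 targets. Of 31 cell cycle genes, 25 rose, 1 fell and 5 did not pass (26 and 1 adjusted over the list alone), with a median of 1.85, and 1.38 and 2.23 within the series. Ccnd1, the cyclin of entry into the cycle, rose by 3.23 ± 0.20 and the replication licensing gene Mcm5 by 2.43 ± 0.28, while the thymidine kinase gene Tk1 fell by 1.27 ± 0.21 on the log2 scale. The list had a camera adjusted p of 5.71e-09, and an adjusted p = 0.219 with an estimated correlation. Of 17 p53 target genes, 15 rose, 1 fell and 1 did not pass (15 and 1 adjusted over the list alone), with a median of 1.34, and 1.20 and 1.25 within the series. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, was Absent on all 4 wild type arrays and at least 9.55-fold higher (limma adjusted p = 1.93e-06). The BH3-only gene Pmaip1 rose by 2.46 ± 0.23 (at least 3.96-fold against the background floor) and Phlda3 by 2.27 ± 0.19, and Bbc3, also of the BH3-only class, fell by 0.73 ± 0.18 on the log2 scale. The p53 list had a camera adjusted p of 1.94e-07, and an adjusted p = 0.139 with an estimated correlation.

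Genes of fetal liver and liver tumours, of bile duct cells and of immediate early responses rose as well. Of 16 oncofetal genes, 12 rose, 0 fell and 4 did not pass (13 adjusted over the list alone), with a median of 2.28, and 1.95 and 2.31 within the series (camera adjusted p = 2.5e-07, adjusted p = 0.139 with an estimated correlation). Besides H19 and Ly6d, Afp, which encodes alpha-fetoprotein, rose by 2.88 ± 0.17 and the Golgi protein gene Golm1 by 2.89 ± 0.15. Of 21 cholangiocyte and progenitor markers, 12 rose, 0 fell and 9 did not pass (12 adjusted over the list alone), with Sox4 at 3.19 ± 0.23 and Anxa13 at 2.77 ± 0.22 besides Ddr1 and Cldn7. Their median was 1.11, and 1.27 and 0.87 within the series (camera adjusted p = 6.25e-05, adjusted p = 0.219 with an estimated correlation). Of 16 immediate early genes, 9 rose, 1 fell and 6 did not pass (11 and 1 adjusted over the list alone), led by the transcription factor genes Klf6 (2.90 ± 0.25) and Jun (2.82 ± 0.31). Their median was 1.44, and 0.92 and 1.59 within the series (camera adjusted p = 0.000304, adjusted p = 0.219 with an estimated correlation). The member that fell, Zfp36 (-0.40 ± 0.13, adjusted p = 0.0338), lost its call without wild type replicate 1 or 4 or labelled knockout replicate 2, 3 or 4, at -0.41 to -0.33 (limma adjusted p of 0.0604 to 0.0931).

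Markers of macrophages and of the matrix rose, and the lists of several other cell types did not pass with camera. Of 24 monocyte and macrophage genes, 19 rose, 0 fell and 5 did not pass (21 adjusted over the list alone), with a median of 1.30, and 0.96 and 2.02 within the series. The matrix metalloproteinase gene Mmp13, under the background floor on all 4 wild type arrays, rose by at least 3.32-fold, Cd9 by 2.89 ± 0.37 on the log2 scale and Cybb, the heme subunit of the phagocyte oxidase, by 2.75 ± 0.20. The list had a camera adjusted p of 1.13e-08, and an adjusted p = 0.219 with an estimated correlation. Of 39 stellate cell and matrix genes, 26 rose, 1 fell and 12 did not pass (30 and 1 adjusted over the list alone), with Lum at 2.16 ± 0.31, Timp3 at 1.22 ± 0.13 and Bgn at 1.14 ± 0.16. The median was 0.99, and 0.56 and 1.34 within the series (camera adjusted p = 1.94e-07, adjusted p = 0.241 with an estimated correlation). The member that fell, Fn1 (-0.40 ± 0.13, adjusted p = 0.0335), lost its call without wild type replicate 1, 2 or 4 or labelled knockout replicate 2, 3 or 4, at -0.40 to -0.33 (limma adjusted p of 0.0603 to 0.0900), and after quantile normalization (-0.11, adjusted p = 0.395). Of 24 interferon response genes, 18 rose, 0 fell and 6 did not pass (18 adjusted over the list alone), with the antiviral gene Oas1a at 2.04 ± 0.12 and the transcription factor gene Irf7 at 1.36 ± 0.13. The interferon list had a median of 0.97, and 0.78 and 0.98 within the series (camera adjusted p = 2.31e-07, adjusted p = 0.219 with an estimated correlation).

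None of the lists of other cell types passed with camera on all 8 arrays, and with fry only the erythroid list did. Of 16 resident Kupffer cell markers, 4 rose, 1 fell and 11 did not pass, 4 and 1 adjusted over the list alone (median 0.38, camera adjusted p = 0.200, adjusted p = 0.726 with an estimated correlation). The complement gene C1qb rose by 0.98 ± 0.18, and the scavenger receptor gene Cd163 fell by 2.14 ± 0.30 on the log2 scale. Without wild type replicate 3 the Kupffer list passed, at a median of 0.58 and an adjusted p of 0.0294. Of 27 endothelial markers, 2 rose, 4 fell and 21 did not pass, 2 and 3 adjusted over the list alone (median -0.12, adjusted p = 0.227, and 0.577 with an estimated correlation), with Clec1b at 0.79 ± 0.16 and Dnase1l3 at -0.63 ± 0.15. Of 6 erythroid markers, Car1 (-2.19 ± 0.28), Alas2 (-2.01 ± 0.38) and Klf1 (-1.26 ± 0.15) fell, 1 rose and 2 did not pass, 3 lower and 1 higher adjusted over the list alone (median -0.88, adjusted p = 0.0799, and 0.219 with an estimated correlation). The erythroid median was lower on every labelled knockout array than on every wild type array, with an exact permutation p of 0.0286 and 0.0446 after adjustment over 39 lists, and the list passed with fry (adjusted p = 0.000688). Of 7 neutrophil markers, all with a difference above 0, 1 rose and 6 did not pass, and 0 passed adjusted over the list alone (median 1.16, camera adjusted p = 0.192, and 0.577 with an estimated correlation). Their median varied widely between arrays, with SDs of 0.78 and 1.08 in wild type and labelled knockout (n = 4 each). S100a8 was at 1.38 ± 0.67 (limma adjusted p = 0.139), at 0.74 without labelled knockout replicate 2, and passed with the deposited array pairs as a block (adjusted p = 0.0268). The neutrophil chemokine gene that rose, Cxcl2 (1.16 ± 0.35, limma adjusted p = 0.0278), lost its call without wild type replicate 1 or 4 or labelled knockout replicate 1, 2 or 3, at 0.98 to 1.18 (adjusted p of 0.0521 to 0.0812), and was at least 1.58-fold higher against the background floor. Of 9 T and NK cell markers 1 rose, Klrd1 at 1.17 ± 0.24, also 1 adjusted over the list alone (median 0.35, adjusted p = 0.519, and 0.790 with an estimated correlation). Of 10 B and plasma cell markers 3 rose, likewise 3 adjusted over the list alone (median 0.08, adjusted p = 0.612, and 0.819 with an estimated correlation), with the antigen presentation genes Cd74 at 0.70 ± 0.17 and H2-Eb1 at 0.50 ± 0.11. Of 5 mesothelium and gallbladder markers 1 rose over all genes and 0 adjusted over the list alone (median -0.17, mean 0.17, adjusted p = 0.762, and 0.867 with an estimated correlation). That gene, Wt1 (1.66 ± 0.57, limma adjusted p = 0.0459), lost its call without wild type replicate 2, 3 or 4 or labelled knockout replicate 1, 2 or 4, at 1.18 to 1.84 (adjusted p of 0.0539 to 0.126), and was at least 1.11-fold higher against the background floor. Too few pancreas (2) and adipocyte (4) markers were tested for a list, but all 6 changed. The pancreatic elastase genes Cela1 and Cela2a were at -1.63 ± 0.32 and -0.66 ± 0.18, and of the adipocyte markers Car3 was at -0.89 ± 0.23, Cebpa, which hepatocytes also express, at -0.85 ± 0.10, Lipe at -0.69 ± 0.16 and Fabp4 at 0.64 ± 0.18. Car3 had a mean wild type log2 signal of 15.16, so high that it need not mark another tissue. The call of Car3 was lost after quantile normalization (-0.49, limma adjusted p = 0.157), and that of Fabp4 without wild type replicate 4 or labelled knockout replicate 1 or 4 (0.52 to 0.55, adjusted p of 0.0575 to 0.0632).

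**Figure D2:**
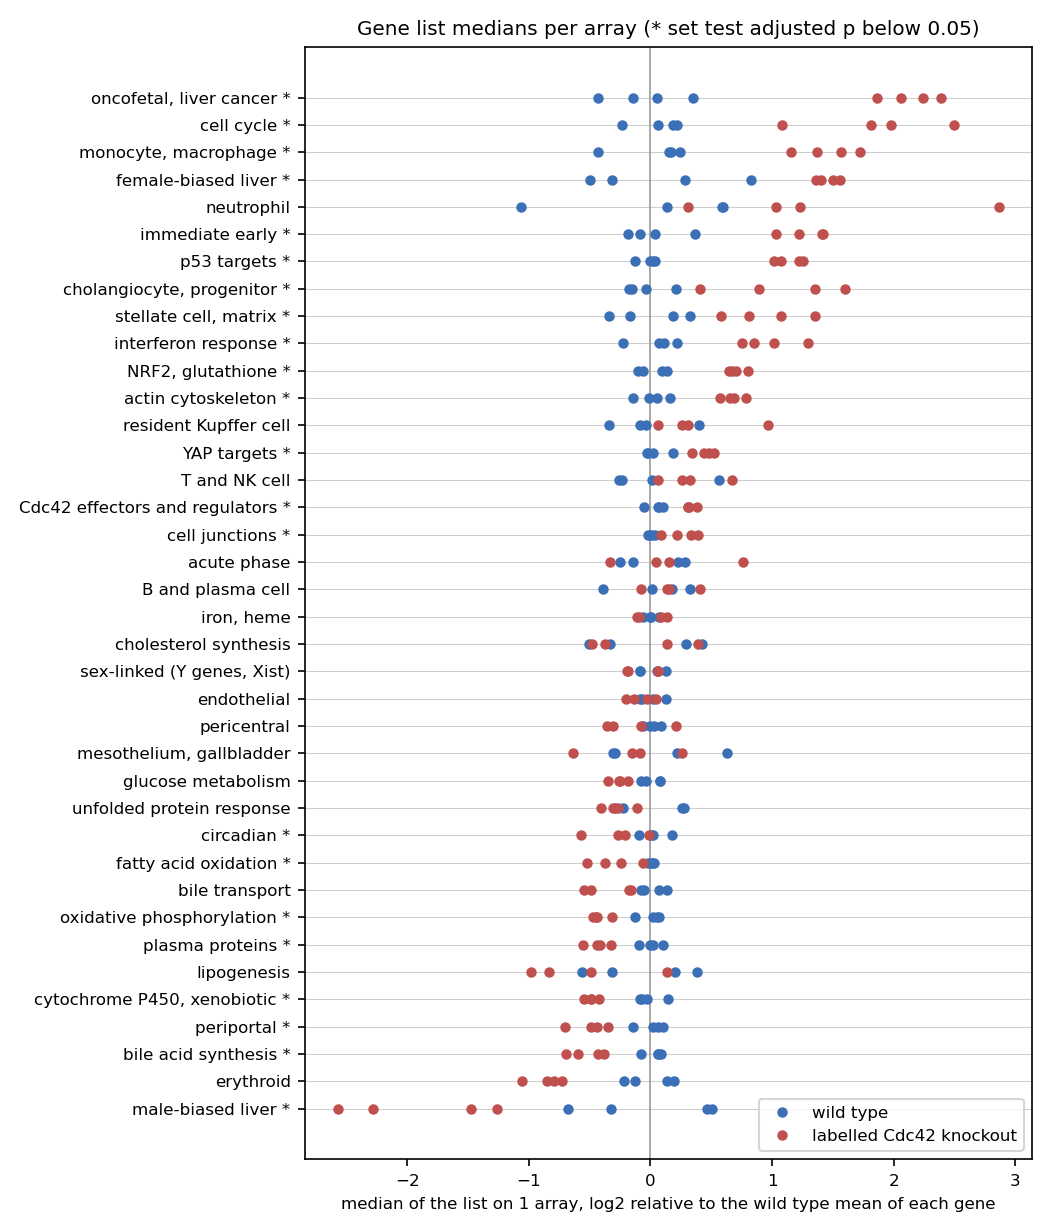
Median of each gene list on each array (log2, relative to the wild type mean of each gene), with 1 point per array (4 wild type, 4 labelled knockout), and an asterisk for lists past camera's adjusted p of 0.05, none of which passed with an estimated correlation. The labelled knockout arrays lie above the wild type arrays for cell cycle genes and below them for male-biased genes.

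Genes with sex-biased expression in mouse liver moved in opposite directions. Of 16 male-biased genes, 14 fell, 0 rose and 2 did not pass, with 14 lower and 1 higher adjusted over the list alone. Their median was -1.95, and -1.77 and -2.16 within the series (camera adjusted p = 1.13e-08, adjusted p = 0.219 with an estimated correlation). Besides Hsd3b5 and Elovl3 (-4.37 ± 0.44), the glucuronosyltransferase gene Ugt2b1 fell by 2.50 ± 0.26 and Nudt7 by 1.25 ± 0.12 on the log2 scale. Of 12 female-biased genes, 7 rose, 0 fell and 5 did not pass (7 adjusted over the list alone), with a median of 1.57, and 1.26 and 1.62 within the series (camera adjusted p = 0.0129, adjusted p = 0.246 with an estimated correlation). With every probe set tested, the median of the female-biased list was 0.86 and its call was lost (camera adjusted p = 0.0916). The sulfotransferase gene Sult2a2 was Absent on all 4 wild type arrays and at least 10.5-fold higher (limma adjusted p = 0.000351), Cyp3a41a rose by 2.68 ± 0.28 and the efflux transporter gene Abcc4 by 1.88 ± 0.23. Sult2a2 and Cyp3a41a belong to families whose members can share probes. Cyp17a1 was at -1.59 ± 0.74 (limma adjusted p = 0.127) and passed without wild type replicate 4 (-2.14, adjusted p = 0.0491) and with the animal number series as a block (adjusted p = 0.00976). The Y-linked genes Ddx3y, Eif2s3y and Kdm5d were Present on all 8 arrays and differed by -0.15 ± 0.10, -0.09 ± 0.09 and -0.11 ± 0.15, and Uty rose by 0.54 ± 0.14 (limma adjusted p = 0.0143), with 3 of 4 probe sets of that sign, a call lost for the mean of its probe sets (0.32, adjusted p = 0.0653). Xist was at a log2 signal of 5.82 against 6.65, a difference of -0.84 ± 0.43 (limma adjusted p = 0.161), from a probe set Present on 7 arrays. The remaining Xist probe sets were Present on 0 arrays, with group means between 1.95 and 3.63, so expression of Xist is not shown. As a list these 5 sex-linked genes had a median of -0.11, with 1 past adjusted over the list alone (camera adjusted p = 0.599, and 0.670 with an estimated correlation).

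**Figure D3:**
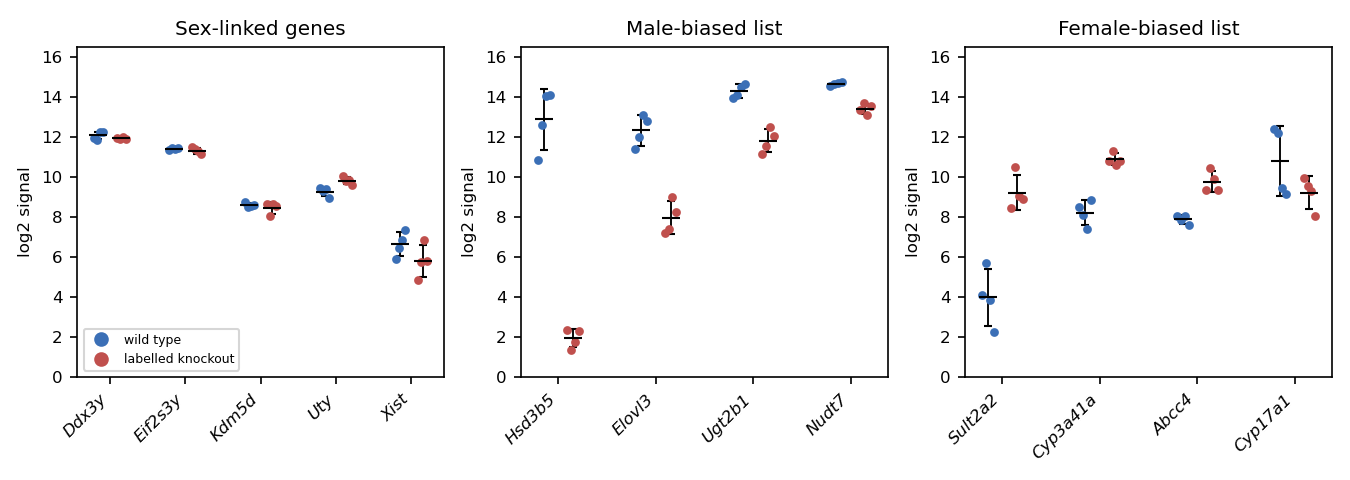
Log2 signal of the sex-linked genes and of members of the male-biased and female-biased lists, as points per array (4 wild type, 4 labelled knockout), with bars at the mean ± SD. Ddx3y, Eif2s3y and Kdm5d overlap between the groups, while the 4 male-biased genes lie lower on every labelled knockout array.

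Genes of hepatocyte metabolism fell, among them many of the most abundant transcripts. Of 37 oxidative phosphorylation genes, 34 fell, 0 rose and 3 did not pass (35 adjusted over the list alone), with a median of -0.43, and -0.42 and -0.43 within the series. Among subunits of the respiratory chain, Ndufb9 fell by 0.66 ± 0.08, Ndufb5 by 0.65 ± 0.08 and Sdha by 0.62 ± 0.09 on the log2 scale. The list had a camera adjusted p of 1.13e-13, and an adjusted p = 0.219 with an estimated correlation. Of 33 plasma protein genes, 26 fell, 0 rose and 7 did not pass (28 adjusted over the list alone), with a median of -0.45, and -0.40 and -0.52 within the series (camera adjusted p = 1.32e-11, adjusted p = 0.219 with an estimated correlation). Plg, Proc and F2, which encode coagulation and fibrinolysis factors, fell by 0.57 ± 0.09, 0.54 ± 0.08 and 0.48 ± 0.07 on the log2 scale. The call of F2 was lost after quantile normalization (-0.12, limma adjusted p = 0.103). Both medians depended on the scaling of the arrays. After quantile normalization the plasma protein median was -0.07 and no longer passed (camera adjusted p = 0.108), and that of oxidative phosphorylation was -0.23 (adjusted p = 1.29e-06). After cyclic loess they were -0.16 and -0.26, both past the threshold (camera adjusted p of 0.00107 and 4.94e-08), and after median centring -0.55 and -0.53, further from 0. The 1214 tested genes with the highest mean signal had a median of -0.23, with 126 genes that rose and 515 that fell, while the genes of lower signal, in groups of about that size, had medians between -0.03 and 0.17. These falls went with the higher share of Present calls and the smaller share of signal in the brightest probe sets of the labelled knockout arrays, 54.2% against 48.6% and 38.4% against 43.4%. The brightest probe sets were the same on every array, so a fall of their own transcripts would also lower that share.

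Metabolic genes of the periportal zone, drug metabolism and bile acid synthesis fell as well. Of 23 periportal genes, 15 fell, 1 rose and 7 did not pass (16 lower and 2 higher adjusted over the list alone), with a median of -0.52, and -0.45 and -0.61 within the series (camera adjusted p = 2.21e-06, adjusted p = 0.219 with an estimated correlation). The histidine catabolism gene Ftcd fell by 1.30 ± 0.11 and Cyp2f2 by 1.97 ± 0.16 on the log2 scale, and Cdh1, which encodes E-cadherin, rose by 1.04 ± 0.18. Of 27 cytochrome P450 and xenobiotic genes, 15 fell, 2 rose and 10 did not pass (16 lower and 4 higher adjusted over the list alone). Cyp2c54 fell by 2.63 ± 0.13 on the log2 scale and Cyp2c55 rose by 2.30 ± 0.38, in a gene family whose members can share probes. The median was -0.42, and -0.35 and -0.58 within the series (camera adjusted p = 6.05e-06, adjusted p = 0.139 with an estimated correlation). After quantile normalization the medians of the periportal and P450 lists were -0.34 and -0.14, still past the threshold. Of 14 bile acid synthesis genes, 9 fell, 0 rose and 5 did not pass (9 adjusted over the list alone), with Cyp8b1 at -3.65 ± 0.40 and Cyp7b1 at -2.39 ± 0.47. Their median was -0.49, and -0.37 and -0.56 within the series (camera adjusted p = 0.000156, adjusted p = 0.139 with an estimated correlation), and -0.25 after quantile normalization (adjusted p = 0.00955). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 0.67 ± 0.41 (limma adjusted p = 0.233), and passed without wild type replicate 2 (1.08, adjusted p = 0.0218).

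The fatty acid oxidation and circadian lists were lower with many members that did not pass, and the mixed list of NRF2 targets and glutathione genes was higher. Of 24 fatty acid oxidation genes, 11 fell, 2 rose and 11 did not pass (12 lower and 2 higher adjusted over the list alone), with a median of -0.30, and -0.36 and -0.21 within the series. Ppara, the nuclear receptor that drives this pathway, fell by 1.12 ± 0.12 and the thiolase gene Acaa2 by 0.59 ± 0.10 on the log2 scale, and Pdk4, which inhibits pyruvate dehydrogenase, rose by 2.62 ± 0.40. The list had a camera adjusted p of 0.000698, and an adjusted p = 0.255 with an estimated correlation, and it was not past the threshold after quantile normalization (-0.11, adjusted p = 0.276) or cyclic loess (-0.13, adjusted p = 0.130). Its median lay at percentile 13.2 of 10000 random lists of genes of like signal (median of these -0.22), against percentiles of 0.15 for oxidative phosphorylation and 0.33 for plasma proteins. Of 15 circadian genes, 5 fell, 0 rose and 10 did not pass (5 adjusted over the list alone), with Hlf at -0.98 ± 0.11 and Dbp at -0.73 ± 0.17. Their median was -0.34, and -0.38 and -0.39 within the series (camera adjusted p = 0.00567, adjusted p = 0.219 with an estimated correlation). Of 26 NRF2 and glutathione genes, 13 rose, 1 fell and 12 did not pass (14 and 2 adjusted over the list alone), with a median of 0.66, and 0.63 and 0.64 within the series. Srxn1, which encodes sulfiredoxin, rose by 2.01 ± 0.14 and the glutathione transferase gene Gsta2 by 1.52 ± 0.18, and Gsta3 fell by 0.54 ± 0.11 on the log2 scale, a call lost after quantile normalization (-0.21, limma adjusted p = 0.116). That list had a camera adjusted p of 0.00669, and an adjusted p = 0.238 with an estimated correlation.

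Lists that did not pass in the main camera test still held genes with large changes. Of 19 bile transport genes, 8 fell and 4 rose, and as many adjusted over the list alone (median -0.30, camera adjusted p = 0.0719, and 0.219 with an estimated correlation, but 0.00766 with fry), with the bile acid uptake transporter gene Slc10a1 at -1.31 ± 0.16, the sterol transporter gene Abcg8 at -1.95 ± 0.23 and the efflux transporter gene Slc51b at 2.85 ± 0.26. Of 22 lipogenesis genes, 6 fell and 4 rose, and as many adjusted over the list alone (median -0.58, adjusted p = 0.0663, and 0.599 with an estimated correlation), and the list passed with the animal number series as a block (adjusted p = 0.00582). The lipogenic regulators Srebf1 and Mlxipl were at -1.85 ± 0.38 and -1.38 ± 0.12, and Pparg and the fatty acid translocase gene Cd36 at 2.19 ± 0.21 and 2.17 ± 0.16. Of 21 glucose metabolism genes, 6 fell and 4 rose, 8 and 4 adjusted over the list alone (median -0.31, adjusted p = 0.0877, and 0.219 with an estimated correlation), with Slc37a4 at -0.92 ± 0.14, Pkm at 1.02 ± 0.16 and Igfbp1 at 1.60 ± 0.30. Of 20 unfolded protein response genes, 4 fell and 2 rose, and as many adjusted over the list alone (median -0.19, adjusted p = 0.0799, and 0.535 with an estimated correlation), with Chac1 at -1.34 ± 0.18 and Atf3 at 2.99 ± 0.55 (2.32 without wild type replicate 4). Its medians within the lower and the higher series were 0.12 and -0.52, the second of which passed (camera adjusted p = 0.00025). Of 28 acute phase genes, 5 rose and 5 fell, 5 and 6 adjusted over the list alone (median 0.28 with a camera direction of down, adjusted p = 0.960, and 0.988 with an estimated correlation), with Cd14 at 3.05 ± 0.18 and Il1rn at 2.08 ± 0.26, against Saa4 at -1.02 ± 0.14 and Crp at -0.75 ± 0.09.

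Of 24 pericentral genes, 8 fell and 2 rose, 9 and 3 adjusted over the list alone (median -0.07, adjusted p = 0.127, and 0.535 with an estimated correlation), with Cyp1a2 at -1.34 ± 0.25 and Slc22a3 at 2.04 ± 0.35. Of 25 cholesterol synthesis genes, 4 fell, 1 of them past adjusted over the list alone, Tm7sf2 at -0.78 ± 0.18 (median -0.08, adjusted p = 0.198, and 0.790 with an estimated correlation). Of 20 iron and heme genes, 5 fell and 3 rose, and as many adjusted over the list alone (median 0.02, -0.08 after median centring, adjusted p = 0.353, and 0.580 with an estimated correlation), with Slc46a1 at -0.84 ± 0.10 and Hjv at 0.62 ± 0.17. Some of these lists passed on all 8 arrays under other settings. With every probe set tested, bile transport (median -0.57, camera adjusted p = 0.000483), lipogenesis (0.0187) and the unfolded protein response (0.00428) passed. With array weights, lipogenesis (camera adjusted p = 0.00861) and cholesterol synthesis (0.0130) passed. Several lists passed when 1 array was left out. Lipogenesis passed without wild type replicate 3 or 4 or labelled knockout replicate 2 (camera adjusted p of 0.00615, 0.0365 and 0.00669), and bile transport without wild type replicate 3 or labelled knockout replicate 3 (0.0495 and 0.0405). The unfolded protein response passed without wild type replicate 1 or 2 or labelled knockout replicate 1 (0.0269, 0.0216 and 0.0437), and cholesterol synthesis without wild type replicate 4 or labelled knockout replicate 2 (0.0356 and 0.0105). Glucose metabolism passed without wild type replicate 3 (0.0301) and the pericentral list without labelled knockout replicate 2 (0.0277).

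Over all 39 lists tested, 23 passed with camera's preset correlation (15 higher, 8 lower), 0 with an estimated correlation (lowest adjusted p = 0.139), and 25 with fry (15 higher, 10 lower), which were the same 23 and the bile transport and erythroid lists. The per-array medians of 25 lists did not overlap between the groups, each with an exact permutation p of 0.0286, and 22 of these lists were among the 23. The circadian list was the exception, with an exact permutation p of 0.0571.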

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

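The tests of the Cdc42, sex-biased and macrophage patterns were chosen after the result was seen, except the test of array scaling and both counts over other splits of the arrays, which were planned.

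Chance is argued against for the number of changed genes, 4145 with the genotype labels against at most 1 in any other split. Of the 35 splits of the arrays into 4 and 4, 1, the real one, gave as many, the smallest share these splits allow. Every other split mixes the genotypes. The real split also separates the Actb and Gapdh measures, the share of Present calls and the share of signal in the brightest probe sets. The number of changed genes therefore does not single out the genotype. Chance cannot be excluded for the number of gene lists by this count, as 7 of the 35 splits, the real one included, gave 23 or more lists, and the highest other split gave 25. The other 6 were among the 16 splits that put 3 arrays of 1 genotype with 1 of the other and so keep part of the genotype difference, with 14 to 25 lists, while the 18 splits with 2 arrays of each genotype on each side gave 3 to 14. The list count with an estimated correlation was 0.

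Cdc42 signal was not lower in the livers labelled as knockout. A single wrong genotype label is argued against by the correlations between arrays, since all 8 arrays had their highest correlation with an array of their own genotype. Signal from the copy that 2 of the probe sets match on chromosome X is argued against by the probe set with no such match, whose lower 95% limit was 83.5% of wild type. Probe sets that read a 3′ part left by the deletion remain a candidate explanation, and the difference between the probe set aligned along the gene and the mean of the others, -0.11 on the log2 scale, cannot tell, because the labels do not give the deleted part. Transcript from cells other than hepatocytes, and an incomplete deletion, stay open and untested.

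Male-biased liver genes fell and female-biased genes rose in labelled knockout liver. Animals of different sex in the groups are argued against by Ddx3y, Eif2s3y and Kdm5d, Present on all 8 arrays with a largest difference of 0.15 on the log2 scale. A lower share of hepatocytes is argued against as the whole cause by the female-biased list, whose median was 1.575 where such a loss would lower both lists (0.86 with every probe set tested, when the list no longer passed). Each animal number series held 2 arrays of each genotype, so a difference between the series cannot by itself set the genotypes apart. The male-biased median was -1.77 within the series nearer to 0. The list did vary with the series, at -0.68 and -0.33 on the wild type arrays of the lower series against 0.51 and 0.46 in the higher. On the labelled knockout arrays it was at -2.28 and -2.57 against -1.48 and -1.26. The genotype remains open as an explanation, as a hypothesis found and tested on the same arrays.

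Monocyte, macrophage and matrix genes rose in labelled knockout liver. A lower share of hepatocytes that raises every other cell type alike is argued against for the macrophage genes, since their median exceeded that of the endothelial list by at least 1.36 on the log2 scale in each labelled knockout array. Blood left in the vessels is argued against by the erythroid median, at most -0.72 in any labelled knockout array, and scaling of the arrays by the macrophage median of 1.35 after quantile normalization. None of the 24 macrophage genes belongs to another list, but 14 of them were called Present or Marginal on all wild type arrays, so resident cells or hepatocytes may supply part of their signal. More macrophages, a change in the macrophages present, and the genotype as such stay open.

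Of 374 sets of 4 arrays tested for an array that stood far from the other 3, 15 had one, where chance gives about 18.7. The number beside each is the gap to the nearest other array as a part of the whole range. In wild type replicate 1, Ubd was at a log2 signal of 1.42 against 5.38 to 5.94 (0.876) and Ces1f at 12.89 against 6.54 to 7.25 (0.888). In wild type replicate 3, Igdcc4 was at 3.76 against 5.70 to 6.03 (0.856) and Krt8 at 12.31 against 12.71 to 12.73 (0.945). That array also had a bile acid synthesis median of -0.07 against 0.06 to 0.08 (0.841), and 41.6% of summed signal in the brightest probe sets against 43.9% to 44.3% (0.857). In wild type replicate 4, S100a8 was at 6.95 against 8.89 to 9.28 (0.831) and the monocyte and macrophage median at -0.43 against 0.16 to 0.24 (0.869).

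In labelled knockout replicate 1, Ccnd1 was at a log2 signal of 12.08 against 12.70 to 12.81 (0.846) and Car3 at 13.49 against 14.47 to 14.56 (0.923). In labelled knockout replicate 2, Klf6 was at 10.11 against 11.23 to 11.43 (0.848), Klf1 at 6.79 against 7.12 to 7.19 (0.835) and Kdm5d at 8.03 against 8.56 to 8.64 (0.869). In labelled knockout replicate 3, C1qb was at 12.47 against 11.99 to 12.06 (0.861) and Cd74 at 12.32 against 11.85 to 11.92 (0.857).

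The genotype difference itself differed between the animal number series for 7 genes in limma's interaction test (1155 at an unadjusted p below 0.05). For Slco1a1 the test gave a difference of 3.27 on the log2 scale (limma adjusted p = 0.0275), but labelled knockout replicates 1 and 2, those of the lower series, were under the background floor. With each signal raised to that floor, the differences were -7.02 and -6.33 in the lower and the higher series, so a larger fall in the lower series is not shown. The other 6 genes, chosen after their values were seen, were Sult1e1 (3.41), Lgals1 (1.76), H2-Q6 (1.67), Gstm3 (1.10), Hsd17b6 (-1.50) and Creld2 (-2.25), as the difference in the higher series minus that in the lower one.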

How the results depend on the processing

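Among the tests with other settings, cyclic loess, the deposited array pairs as a block and each animal number series alone were chosen after the result was seen, while fry and camera with an estimated correlation were named with the main tests and counted as alternatives only later. The count of changed genes, 4145 at first, lay between 3383 and 4609 under the scalings, floors, filters and model settings tried on 1 probe set per gene and all 8 arrays, and between 3166 and 3871 with 1 array left out (1874 to 2331 higher, 1292 to 1540 lower, 728 to 905 higher and 233 to 273 lower by at least 2-fold). Of the 4145 genes, 3346 were called again with the same sign after quantile normalization, 3608 after median centring, 3466 after cyclic loess and 4126 with the series as a block. Testing every probe set gave 6877 calls, 4068 higher and 2809 lower, with 1390 higher and 454 lower by at least 2-fold, from more tests per gene, and no filter gave 439 lower by at least 2-fold, from more genes tested. The lower animal number series alone gave 2236 (1292 higher, 944 lower), and the higher one 1077 lower genes, from 2 arrays against 2. The list count was 0 with camera's estimated correlation and 22 to 27 with 1 array left out. For the second Cdc42 probe set the difference was 0.082 after quantile normalization, 0.090 after cyclic loess and 0.039 in the higher series alone, and for the third -0.051 after median centring and -0.10 in the lower series alone. With 1 array left out the ranges for the 3 probe sets were 0.07 to 0.17, -0.10 to -0.00021 and -0.032 to 0.10. The 3′ minus 5′ difference between genotypes was -0.11 for Actb after quantile normalization (exact permutation p = 0.0571), and with 1 array left out -0.21 to -0.16 for Actb and -0.15 to -0.094 for Gapdh. Actb turned to 0.063 and Fbp1, a gluconeogenic gene at -0.34 ± 0.08 before, to 0.020 after quantile normalization (limma adjusted p of 0.469 and 0.862), and the cause of both was not tested. For the 249 genes taken by the naming rule or as growth hormone targets, 5853 values kept direction and side of the threshold, 266 lost and 54 gained a call, 45 moved and 2 reversed. Most of these genes were picked by fold or p, so these counts do not stand for all genes. For single lists the numbers were 918, 13, 25, 18 and 0. Deviations from the group means correlated at 0.129, 0.184, 0.17 and 0.074 in the deposited array pairs. Across genotypes, they correlated at 0.039 to 0.184 for arrays of the same series and at -0.178 to -0.068 for arrays of different series. The pairs thus did not stand out from their series and were not taken as a design, and as a block they gave 4281 changed genes. With genotype in the fit, 162 genes differed between the series (limma adjusted p below 0.05). The other deposited table holds equal values, so that alternative was not run. Signal near background limits the genes called Absent in 1 group, for which bounds are given.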

Other observations

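The tests of annotation terms and of the chromosome segment were chosen after the result was seen. The prediction on growth hormone signalling was written before its result was seen, for a hypothesis added later than the main tests.

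Other gene groups, from the annotation terms of the deposited table, moved with those described. Of 417 terms with 10 to 300 tested genes, 21 passed with camera (10 higher, 11 lower) and 0 with an estimated correlation (lowest adjusted p = 0.698). Genes of translation were lower in labelled knockout liver, with 69 of 245 that fell and 21 that rose (median -0.15, camera adjusted p = 0.00115), a call lost after quantile normalization (camera adjusted p = 0.304). Of 22 tricarboxylic acid cycle genes, 11 fell and 0 rose (median -0.26, camera adjusted p = 0.0167), also lost after quantile normalization (camera adjusted p = 0.417). Of 15 amino acid metabolism genes, 8 fell and 0 rose (median -0.48, camera adjusted p = 0.00128, and 0.0455 after quantile normalization).

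Among the terms that were higher, 54 of 128 mitosis genes rose and 1 fell (median 0.38, camera adjusted p = 0.000234). Of 38 genes that promote the NF-kappaB cascade, 16 rose and 2 fell (median 0.22, camera adjusted p = 0.0430, and 0.0545 after quantile normalization). Of 36 genes that regulate cell shape, 18 rose and 4 fell (median 0.45, camera adjusted p = 0.0473, and 0.0648 after quantile normalization). Of 38 extracellular matrix organization genes, 15 rose and 2 fell (median 0.28, camera adjusted p = 0.0431).

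A hypothesis for the fall of male-biased genes is that growth hormone signalling through STAT5 was lower in labelled knockout liver, which would lower its direct targets Socs2 and Cish. The higher of their differences was 1.10 ± 0.37 for Socs2 (limma adjusted p = 0.0420), with 2 of 3 probe sets of that sign, and Cish was at 0.29 ± 0.40 (limma adjusted p = 0.613). Neither gene was lower on all 8 arrays, where the hypothesis predicts a fall of both. The call of Socs2 was lost in 16 of 25 alternatives (adjusted p from 0.00818 to 0.128 over the 25). Among these were the fits without wild type replicate 1, 2 or 4 or labelled knockout replicate 1, 3 or 4 (0.81 to 1.16). With wild type SDs of 0.77 for Socs2 and 0.92 for Cish (n = 4), the test may rest on few arrays. It cannot decide whether signalling was lower.

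A chromosome segment carried along with the targeted Cdc42 allele could change genes near it. Of 167 genes within 10 Mb of Cdc42, 56 changed (33.5%), against 4041 of 11780 elsewhere (34.3%), with a 1-sided Fisher exact p of 0.612. That gives no sign of a segment that changes many genes. With 34.3% changed elsewhere, the count could not show a segment that changes only a few. The first principal component of 23600 probe sets held 56.4% of the variance and separated the genotypes, and the second, with 13.8%, separated the animal number series.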
